A study of Mus musculus with 3 samples.

How the data were processed

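Kidney total RNA of 3 BALB/c mice, taken 7 days after injection of antibody against the glomerular basement membrane (anti-GBM), was hybridised to 3 dual-colour expression arrays, 1 mouse per array. Per the labels, the RNA of each nephritic mouse carried Cyanine-5 (red), and RNA pooled from the kidneys of 5 normal mice carried Cyanine-3 (green) on each array. No array had the dyes exchanged. The control pool therefore counts as 1 control sample, and a dye effect cannot be separated from the comparison.

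The deposited table holds 1 value per array for each of 16281 features. The values were read as log2 ratios that the authors had already normalized. The scanner, image analysis, background correction, normalization, filters, log base and direction of the ratio are not given in the sources used here. The direction, nephritic over control, was taken as likely from the dyes in the labels, because a ratio of red over green is usual. If the ratio was formed the other way, every direction reported here turns together. The base was taken as 2 from the size of the values. The value exceeded by 1% of measured features on an array would correspond to 2.24 to 2.49 fold on the log2 scale and to 14.6 to 20.8 fold on a log10 scale. Tests, ranks and counts without a fold threshold do not depend on the base, but every fold change does.

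An exact 0 stood in 25.7%, 26.7% and 32.8% of the cells of replicates 1, 2 and 3. These cells were read as not measured, because measured ratios carry many decimals. This reading was chosen after the values had been looked at, and the counts of changed genes depend on it more than on most other choices. With the zeros set aside, the median was 0.02 on each array. A value other than 0 was present on all 3 arrays for 9936 features, on 2 arrays for 1814 and on 1 array for 1531, and 3000 features were at 0 on all arrays. Only features measured on all 3 arrays were tested. Signal intensities were not used here, so the signal behind a ratio is unknown, and the number of arrays limits the precision.

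Genes were named from the platform annotation. It gave 1 gene symbol for 13738 features, several for 52 and none for 2491. Through the Entrez identifier, 13694 features matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Features with several symbols were used only at the feature level. Genome positions were not used. Log2 ratios of all features with the same gene symbol were averaged on each array, which gave 7432 genes, 1144 of them with more than 1 feature.

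Changes were tested in R 4.3.3 with limma 3.58.1, as a linear model with an intercept only on the log2 ratios against 0, with the empirical Bayes variance at its default prior, two-sided, and Benjamini-Hochberg adjustment. An adjusted p under 0.05 counted as changed. With 3 arrays there were 2 residual degrees of freedom per gene. The prior had a residual standard deviation of 0.155 and 6.19 degrees of freedom. The test covers the spread between the nephritic mice and their arrays and leaves out the spread between control mice.

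The 31 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera from limma at its preset correlation of 0.01, over members measured on all 3 arrays, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, the self-contained test fry, and the position of each median among 10000 random lists of the same size stood beside it. The lists hold 489 measured genes, 17 of them in more than 1 list. The genes named were the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and the same sign on all 3 arrays, the 3 members of each list with the smallest p, and 17 fixed markers whatever their values, of which 1 is not reported here. Other members are named where they stood against their list or were few, and these were chosen after their values had been seen.

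The procedure was tested on simulated data with 200 changed genes among 7432. It called 52.2% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 97.0% of those changed by 2, and 1.86% of its calls were unchanged genes. The simulated arrays were drawn independently around the true change, with each gene's observed SD taken as its true SD. Only 200 genes were changed, while 36.3% of genes were called in the data. The percentages of changed genes called therefore need not hold for the data. The simulated arrays also held no error shared by the 3 arrays, as 1 control pool and 1 dye orientation can give. The 1.86% leaves such false calls out. The list test gave a p under 0.05 for 2.90% of unchanged lists, whose simulated genes were independent. In the data, the estimated correlations ran from -0.135 for the sex-dimorphic list to 0.461 for MHC class I. The 2.90% therefore does not show how the preset correlation performs on lists of correlated genes. A list of 20 genes shifted by 0.5 was called in 100% of 50 draws with the preset correlation and in 0% with an estimated correlation. With 3 arrays the latter test therefore had no power for such a shift in independent genes.

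Alternatives tried were centring or scaling the arrays, features measured on at least 2 arrays, leaving out each replicate, a robust prior, limiting extreme values, fold thresholds, a stricter adjusted p, no sharing of variance, and the median feature per gene. For an even number of features, the median feature was the lower of the middle pair, so this setting leans toward lower values. The reading of exact zeros as values and the removal of a run of neighbouring features were added after seeing the data. With exact zeros as values, all features entered the fit, also the 3000 at 0 on all arrays. Features without spread change the variance shared between genes, so a gene can lose its call without a zero of its own. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.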

Results

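Gene expression was measured in the kidneys of 3 mice 7 days after injection of anti-GBM antibody, which binds the glomerular basement membrane and produces an immune glomerulonephritis. Each nephritic kidney was compared on 1 dual-colour array with the pooled kidney RNA of 5 normal mice. Values are mean log2 ratios of nephritic over control kidney ± SD over the 3 mice, and a log2 ratio of 1 is a doubling under the reading of the values described with the processing. Across features, the log2 ratios of the 3 arrays had Pearson correlations of 0.771 to 0.836 and Spearman correlations of 0.686 to 0.770 (9936 features). The 3 ratios share 1 control pool and 1 dye orientation, which alone make such correlations positive, and their size without any change in the nephritic kidney could not be measured on these arrays. Features are not independent replicates, so no p is given for these correlations. With the upper quartile of absolute mean ratios left out, the lowest Pearson correlation was 0.358, but choosing features by the means of the same arrays in itself lowers it.

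The kidney transcriptome differed widely from the control pool on day 7. Of 7432 genes, 1462 were higher and 1236 were lower in nephritic kidney (limma, adjusted p under 0.05), which together is 36.3% of the genes. With array medians centred, 1288 were higher and 1352 lower, so the balance between rises and falls depends on the scaling. Most changes were small. A change of at least 2-fold was found for 128 of the higher and 86 of the lower genes. All 3 arrays had the same sign for 63.7% of genes, a share that the control pool and dye orientation common to the arrays also raise. At the level of single features, 1950 were higher and 1625 lower. Among the changed genes, 398 had more than 1 feature, and in 27 of these the features differed in sign. These genes were called on the average of their features, which favours features that agree. Of 366 genes chosen by 1 called feature instead, 79.8% had a partner feature of the same sign.

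The largest rise was that of Ccl20, a chemokine for CCR6-bearing lymphocytes and dendritic cells, at 2.40 ± 0.15, or 5.28-fold (adjusted p = 1.01e-05). It was followed by the lactate and pyruvate transporter Slc16a1 (2.20 ± 0.03, 4.59-fold), the chloride channel regulator family member Clca3a2 (2.03 ± 0.16) and the immediate early transcription factor Egr1 (2.00 ± 0.21). Sox9, a transcription factor of regenerating tubule epithelium, reached 1.93 ± 0.63, with its lowest value on replicate 1 and 2.26 and 2.34 on replicates 2 and 3. The other genes among the 12 largest rises were Junb (1.93 ± 0.28), the acute phase gene Saa2 (1.92 ± 0.20), the neutrophil chemokine Cxcl2 (1.86 ± 0.14), the leukocyte adhesion molecule Vcam1 (1.86 ± 0.06), the metalloprotease Adam8 (1.85 ± 0.38), the fibrillar collagen Col3a1 (1.82 ± 0.16) and the interleukin-1 family cytokine Il1f6 (1.79 ± 0.31). The adjusted p of the 12 genes was at most 0.000262. The order of these rises depends on how exact zeros are read. When they are taken as values, a setting chosen after seeing the data, features at 0 enter the averages, and Ccl20 was at 1.29, Cxcl2 at 0.93, Adam8 at 0.93 and Il1f6 at 0.91. Adam8 was then not called. Sox9 was not called either, at an unchanged mean of 1.93, so no zero had entered its average. Several genes named below also lost the call at an unchanged mean. Such a loss comes from the fit over all genes, not from the gene's own values.

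The 12 largest falls were led by Sdc3 (from -3.61 to -2.22 on the 3 arrays, SD 0.71), Hes1 (-2.60 ± 0.66), Lhx1 (-2.44 ± 0.57) and Nfkbib (-2.26 ± 0.48). These 4 genes and Ebi3 (-1.90 ± 0.74) were each measured by 1 feature, and these 5 features lay among neighbours on the array, at feature numbers 15762 to 15770. In that run from 15760 to 15773, 9 of 11 measured features had a mean under -1, and 3 other genes of the run were at -0.35 to 0.16 by features elsewhere on the array. Igfbpl1 (-2.24 ± 0.40) was measured by feature 15720, also not far from the run. Outside this stretch the largest falls were those of the fatty acid desaturase Scd1 (-2.14 ± 0.40), the small proteoglycan Nepn (-2.13 ± 0.19), the organic anion transporter Slco1a6 (-2.12 ± 0.54), the carboxylesterase Ces1g (-1.99 ± 0.19), the pyroglutamyl peptidase Pgpep1 (-1.98 ± 1.03) and the skeletal muscle myosin Myh1 (-1.96 ± 0.56). The adjusted p of the 12 falls was at most 0.00182, for Pgpep1, whose replicates ranged from -2.87 to -0.85. Pgpep1, when exact zeros were taken as values, was at -0.99, and only Nepn and Ces1g of the 12 were still called. The other genes that lost the call kept their means.

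**Figure D1:**
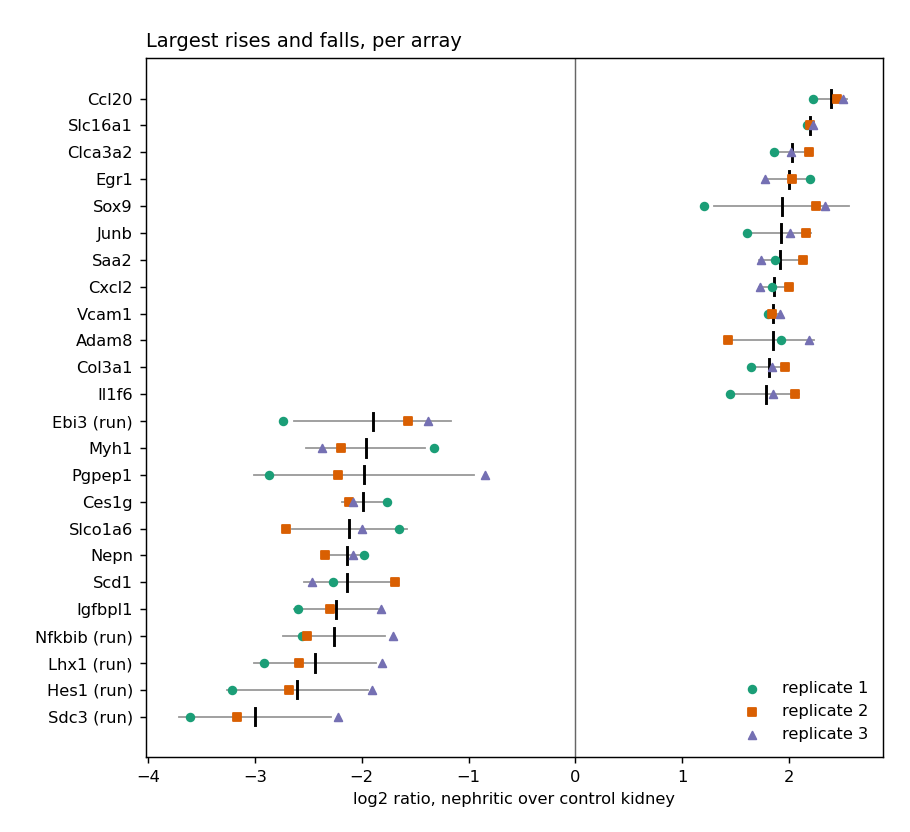
Log2 ratio of nephritic over control kidney for the 12 largest rises and the 12 largest falls. Each symbol is the array of 1 mouse, the black tick is the mean and the grey line spans 1 SD to each side. Genes marked "run" are measured by a feature inside the run of neighbouring features from 15760 to 15773; Pgpep1 has the widest spread, from -2.87 to -0.85.

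**Figure D2:**
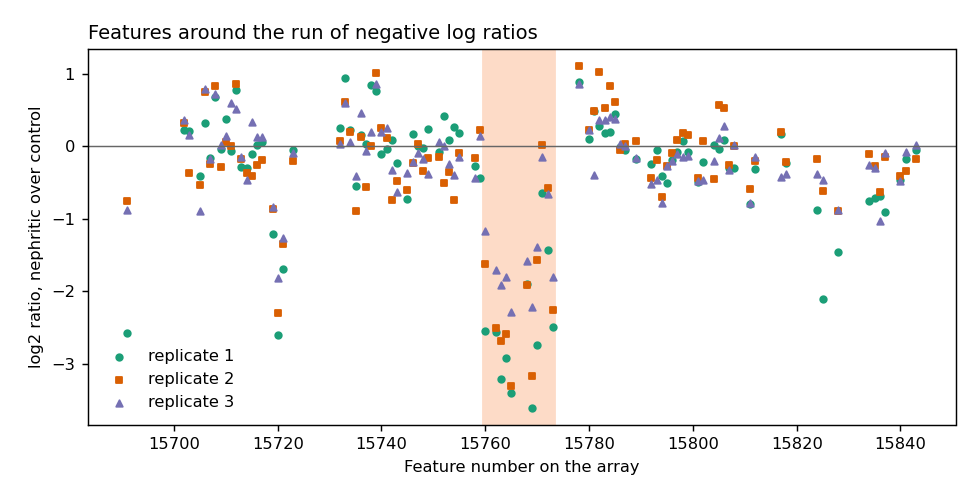
Log2 ratio of nephritic over control kidney by feature number on the array, each symbol 1 mouse. The shaded run from 15760 to 15773 holds 11 features measured on all 3 arrays with a median of -2.19, below the features on either side apart from a few such as Igfbpl1 at feature 15720.

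Genes of tubular injury and the acute phase rose as a group. Of 20 measured members 19 were higher and 0 lower, also when adjusted over the list alone, and the median was 1.05. The calcium-binding protein S100a6 rose by 1.71 ± 0.04, Saa2 by 1.92 ± 0.20 and the fibrinogen chain Fga by 1.40 ± 0.07. Lcn2, the injury marker also called NGAL, rose by 1.43 ± 0.23, or 2.70-fold. Il18 (-0.10) did not pass the test. S100a6 was at 1.05 by the lower of its 2 features, and with exact zeros as values it was not called. The list stood above other genes with a camera adjusted p of 9.89e-13, while with an estimated correlation the adjusted p was 0.384.

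Immediate early and heat shock genes, which respond to stimuli within minutes and also to tissue handling, were higher as a list too. Among 20 measured members 14 were higher and 1 lower, also when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 1.86e-05; adjusted p = 0.384 with an estimated correlation). Egr1 rose by 2.00 ± 0.21, Junb by 1.93 ± 0.28 and Myc by 1.78 ± 0.18. The member that fell was the phosphatase Dusp1 (-0.51), and Fos (-0.06) and the heat shock genes Hspa1a (-0.04) and Hspa1b (-0.20) did not pass.

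Matrix genes and cell cycle genes were higher. Of 37 measured genes of extracellular matrix and fibrosis 19 rose and 1 fell, and adjusted over the list alone 23 rose and 3 fell. The median was 0.31 (camera adjusted p = 2.12e-05; adjusted p = 0.413 with an estimated correlation). Fibronectin, Fn1, rose by 1.62 ± 0.05, Col3a1 by 1.82 ± 0.16 and the TGF-beta induced matrix protein Tgfbi by 1.38 ± 0.06. The basement membrane collagen Col4a1 rose by 0.82 ± 0.09 and the fibrillar collagen Col1a1 by 0.34 ± 0.05, a call lost without replicate 2 (0.31) and without replicate 3 (0.36). Thbs1 was the member that fell (-0.47). Of 30 measured cell cycle genes 17 rose and 0 fell, and 18 rose when adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.000209; adjusted p = 0.493 with an estimated correlation). Fry did not call this list. The proliferation marker Mki67 rose by 1.18 ± 0.37 and the mitotic cyclin Ccnb2 by 0.79 ± 0.24. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 1.48 ± 0.16. Cdkn1a, when exact zeros were taken as values, was at 0.57 and Ccnb2 at 0.40, and Cdkn1a, Mki67 and Ccnb2 were not called.

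Complement and macrophage genes rose. Of 15 complement genes 10 were higher and 0 lower, and 11 were higher when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00014; adjusted p = 0.384 with an estimated correlation). The regulator Cfi rose by 1.32 ± 0.16, the classical pathway component C4b by 1.19 ± 0.15 and the protease C1ra by 0.90 ± 0.15, or by 0.45 with exact zeros as values. Of 21 macrophage markers 14 were higher and 0 lower, and adjusted over the list alone 14 were higher and 1 lower. The median was 0.54 (camera adjusted p = 0.000135; adjusted p = 0.473 with an estimated correlation). The lysozyme gene Lyz2 rose by 1.64 ± 0.22, the lysosomal protease Ctss 2.82-fold (SD 0.11 on the log2 scale) and the galectin Lgals3, also in the tubular injury list, by 0.94 ± 0.07. The member lower when adjusted over the list alone was Csf1r (-0.23), and Adgre1 (0.10), Ptprc (0.14), Spi1 (0.13), Fcgr2b (-0.14), Cd53 (-0.10) and Msr1 (-0.00) did not pass.

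Antigen presentation genes were higher too. In MHC class II, 7 of 8 measured members were higher and 1 lower, also when adjusted over the list alone (median 0.64; camera adjusted p = 0.00331; adjusted p = 0.384 with an estimated correlation). H2-Eb1 rose by 0.80 ± 0.10, H2-Ea by 0.73 ± 0.06, H2-Aa by 0.67 ± 0.08 and the invariant chain Cd74 by 0.62 ± 0.04. The class II transactivator Ciita was the member that fell (-0.41). In MHC class I, 6 of 8 were higher and 0 lower, also when adjusted over the list alone (median 0.74; camera adjusted p = 0.00145; adjusted p = 0.455 with an estimated correlation). H2-K1 rose by 0.91 ± 0.11, H2-D1 by 0.83 ± 0.08 and the peptide transporter Tap2 by 0.79 ± 0.07. H2-K1 was at 0.56 with features measured on at least 2 arrays, and at 0.39 and not called with exact zeros as values. Features for closely related H2 genes can share signal. Of 21 interferon response genes 10 were higher and 0 lower, and 11 were higher when adjusted over the list alone (median 0.25; camera adjusted p = 0.00359; adjusted p = 0.413 with an estimated correlation). Ifi204 rose by 0.86 ± 0.07 and the transcription factors Irf1 and Irf8 by 0.78 ± 0.07 and 0.72 ± 0.05.

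Components and targets of NF-kB rose, with 13 of 21 measured members higher and 1 lower, also when adjusted over the list alone (median 0.40; camera adjusted p = 0.000298; adjusted p = 0.413 with an estimated correlation). Vcam1 rose by 1.86 ± 0.06 and the apoptosis inhibitor Birc3 2.30-fold (SD 0.23 on the log2 scale), and the inhibitor Nfkbie was the member that fell (-0.59). Chemokines and cytokines were mixed. Of 23 measured, 10 were higher and 3 lower, also when adjusted over the list alone, with a median of 0.18. The camera adjusted p was 0.0271, against 0.536 as the adjusted p with an estimated correlation, and the call was lost without replicate 2, where the median was 0.18. It was also lost under fry, against random lists, with features measured on at least 2 arrays (median 0.17) and with exact zeros as values (median 0.13). Cxcl2 rose by 1.86 ± 0.14, the monocyte chemokine Ccl2 by 1.22 ± 0.25 and Il1b by 0.88 ± 0.26. The members that fell were Cxcl12 (-0.46), Il1a (-0.31) and Ccl19 (-0.28), and Tnf (0.05) did not pass. Il1b was at 0.58 by the lower of its 2 features. Cxcl2, when exact zeros were taken as values, was at 0.93, and Ccl2, Il1b and Birc3 were not called.

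Lists of markers of other leukocytes did not pass camera, while fry, which does not compare a list with other genes, called the neutrophil list and the T cell and NK cell list. Of 12 neutrophil markers 3 were higher and 2 lower, also when adjusted over the list alone (median 0.01; camera adjusted p = 0.689). Those that rose were S100a9 (1.46 ± 0.35), Lcn2 (1.43 ± 0.23) and S100a8 (0.64 ± 0.28). Lcn2 is also expressed by injured tubules. S100a8 was at 0.15 and not called by the lower of its 2 features alone, so its other feature lay above the average. The granule genes Ngp (-0.38) and Ltf (-0.30) fell. Of 9 T cell and NK cell markers 3 rose, Cd8a by 0.98 ± 0.11, Il7r by 0.58 ± 0.17 and Cd6 by 0.44 ± 0.12, and 0 fell (3 higher and 1 lower when adjusted over the list alone; median 0.01; camera adjusted p = 0.341). Of 10 B cell and plasma cell markers 3 rose and 3 fell (3 and 4 when adjusted over the list alone; median -0.06; camera adjusted p = 0.936). Sdc1, which plasma cells and epithelia both carry, rose by 1.22 ± 0.25, the transcription factor Xbp1 by 0.49 ± 0.06 and the adaptor Blnk by 0.52 ± 0.16, while Cd22 (-0.37), Cd37 (-0.31) and Ighm (-0.27) fell. Cd8a was at 0.61 with features measured on at least 2 arrays. Cd8a, when exact zeros were taken as values, was at 0.46, Cd6 at 0.19, S100a9 at 0.96 and Blnk at 0.26, and S100a9, S100a8, Il7r, Sdc1 and Blnk were not called.

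**Figure D3:**
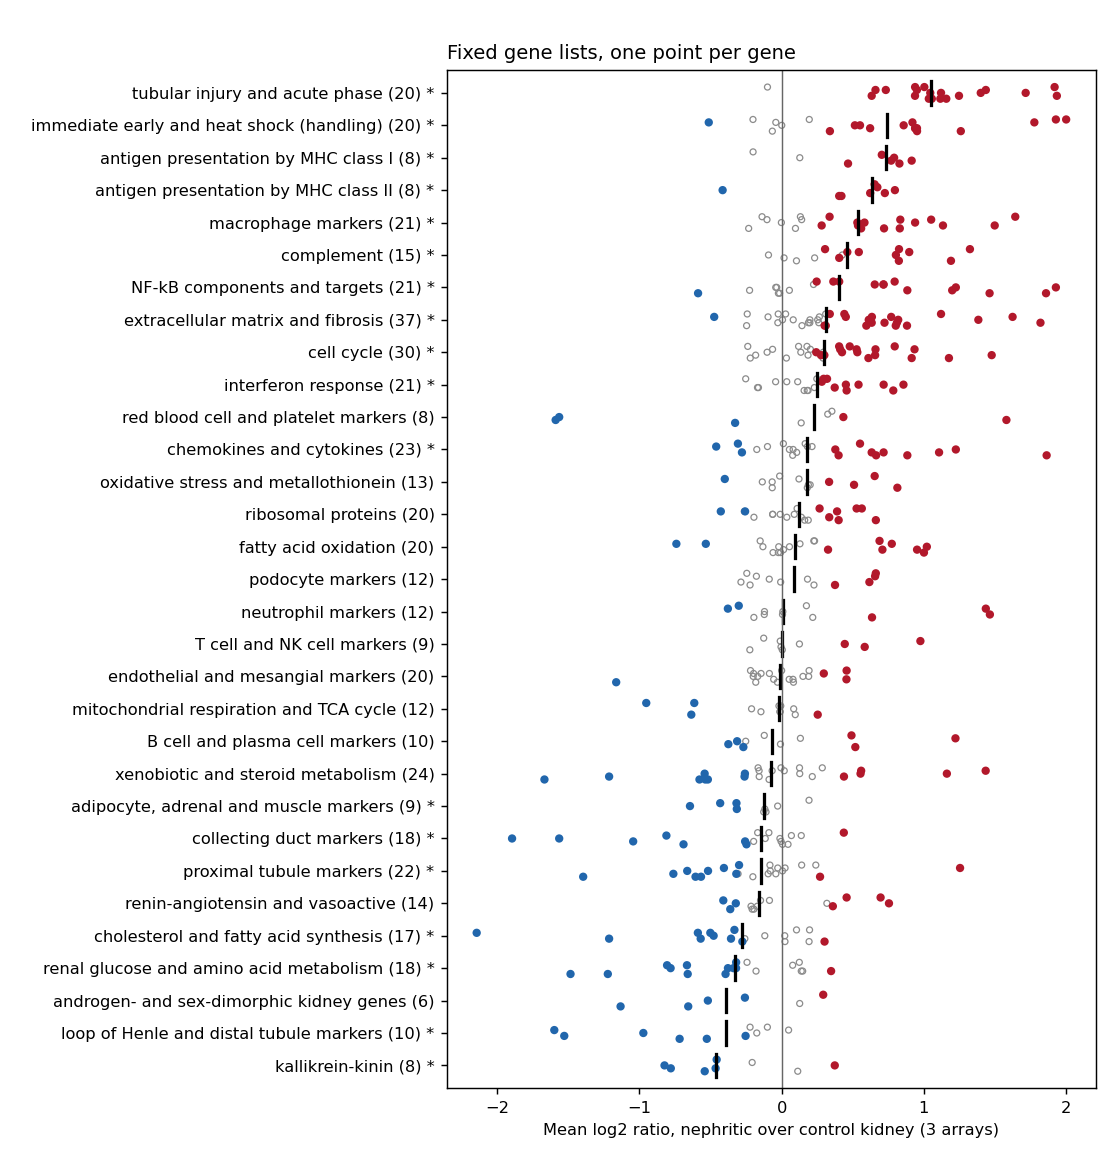
Mean log2 ratio of nephritic over control kidney for each gene of the 31 fixed lists, with the number of measured genes in parentheses. Filled red and blue points are genes higher and lower at an adjusted p under 0.05, open grey points did not pass, black bars are list medians, and an asterisk marks a camera adjusted p under 0.05. Medians run from 1.05 for tubular injury and acute phase to -0.46 for kallikrein-kinin.

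Markers of the distal nephron and collecting duct were lower as lists. Of 10 markers of the loop of Henle and distal tubule 6 fell and 0 rose, and 7 fell when adjusted over the list alone (median -0.39; camera adjusted p = 0.000209; adjusted p = 0.384 with an estimated correlation). Egf, made in these segments, was at -1.60 ± 0.07, a 3.02-fold lower level. The calcium-binding protein Pvalb was at -1.53 ± 0.22 and the loop cotransporter Slc12a1 at -0.97 ± 0.21. Egf and Slc12a1, when exact zeros were taken as values, were not called, and the mean of Egf was over 1.5 times closer to 0. Pvalb is also a skeletal muscle gene, and the muscle gene Myh1 was at -1.96, while the abundant muscle genes Mylpf (-0.11) and Myh4 (0.19) did not pass. Of 22 measured muscle genes, Pvalb among them, 9 were lower and 2 higher. Signal was not used, so Mylpf and Myh4 may lie at background, and a part of muscle in the fall of Pvalb stays open. Of 18 collecting duct markers 7 fell and 1 rose, also when adjusted over the list alone (median -0.14; camera adjusted p = 0.00743; adjusted p = 0.384 with an estimated correlation), and 10 did not pass. Against random lists this call was lost. The water channel Aqp4 was at -1.89 ± 0.41, the anion exchanger Slc4a1 at -1.56 ± 0.06 and the proton pump subunit Atp6v1b1 at -0.81 ± 0.16. The sodium channel subunit Scnn1g was the member that rose (0.44), and Aqp2 (0.01) did not pass. Slc4a1 is also a red cell gene, and the red cell gene Car1 was at -1.59 ± 0.19, while the globin genes Hba-a1 (0.32) and Hbb-b2 (0.35) did not pass. Slc4a1, when exact zeros were taken as values, was at -0.78, and Aqp4 and Atp6v1b1 were not called.

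Proximal tubule markers were lower as a list, with 9 of 22 lower and 2 higher, also when adjusted over the list alone (median -0.15; camera adjusted p = 0.0169; adjusted p = 0.522 with an estimated correlation). Fry did not call this list. The phosphate cotransporter Slc34a1 was at -1.39 ± 0.30, or 2.63-fold lower, and the sodium-proton exchanger Slc9a3 at -0.76 ± 0.05. The sulfate transporter Slc13a1 rose by 1.25 ± 0.17 and the urate transporter Slc22a12 by 0.27. Kallikrein-kinin genes had 5 of 8 members lower and 1 higher, and 6 lower and 1 higher when adjusted over the list alone (median -0.46; camera adjusted p = 0.0117; adjusted p = 0.413 with an estimated correlation). Klk1b21 was at -0.82 ± 0.04, Klk1b9 at -0.78 ± 0.16 and Klk1b27 at -0.54 ± 0.04, members of a gene family alike enough in sequence to share signal. Kng1, which encodes kininogen, was the member that rose (0.37). Slc13a1, when exact zeros were taken as values, was at 0.56, and Slc34a1 and Klk1b9 were not called.

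Of the metabolic lists, renal glucose and amino acid metabolism and cholesterol and fatty acid synthesis were lower. Of 18 genes of renal glucose and amino acid metabolism 11 fell and 1 rose, also when adjusted over the list alone (median -0.33; camera adjusted p = 0.00145; adjusted p = 0.440 with an estimated correlation). Dimethylglycine dehydrogenase, Dmgdh, was at -1.22 ± 0.14, the gluconeogenic enzyme Fbp1 at -0.78 ± 0.06 and Bhmt at -0.66 ± 0.16, and Arg2 was the member that rose (0.35). Of 17 genes of cholesterol and fatty acid synthesis 9 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone (median -0.28; camera adjusted p = 0.00426; adjusted p = 0.384 with an estimated correlation). Scd1 was at -2.14 ± 0.40, the sterol demethylase Cyp51 at -1.21 ± 0.05 and Fasn at -0.59 ± 0.03, and the sterol enzyme Sqle rose (0.30). Fbp1, when exact zeros were taken as values, was at -0.39, and Bhmt and Scd1 were not called.

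Markers of fat, adrenal and muscle, tissues that lie near or around a kidney, were also lower as a list. Of 9 measured 4 fell and 0 rose, also when adjusted over the list alone (median -0.13; camera adjusted p = 0.0347; adjusted p = 0.413 with an estimated correlation). The call was lost without replicate 3, where the median was -0.14, with exact zeros as values, where it was -0.09, and against random lists. Retn was at -0.64 ± 0.18, Tnnt3 at -0.43 ± 0.11 and Mc2r at -0.32 ± 0.11, and Fabp4 also fell (-0.31). Mc2r was not called without replicate 2 (-0.35), without replicate 3 (-0.26) or with the arrays scaled (-0.35). Mc2r, when exact zeros were taken as values, was at -0.06 and Tnnt3 at -0.22, and Mc2r, Tnnt3 and Retn were not called.

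Fatty acid oxidation did not pass as a list, with 7 of 20 genes higher and 2 lower, and 8 and 2 when adjusted over the list alone (median 0.09; camera adjusted p = 0.137). Acot1 rose by 1.02 ± 0.20 and Pdk4, a kinase that restrains pyruvate oxidation, by 0.95 ± 0.13, while the mitochondrial coactivator Ppargc1a (-0.74 ± 0.10) and Fabp3 (-0.53) fell. Without replicate 3 this list passed, with a median of 0.13. Of 12 genes of mitochondrial respiration and the TCA cycle 3 fell, Sucla2 (-0.95 ± 0.28), Atp5b (-0.63 ± 0.02) and Ndufa1 (-0.61 ± 0.23), and Ndufa9 rose (0.25), also when adjusted over the list alone (median -0.02; camera adjusted p = 0.165). Among 6 androgen-dependent and sex-dimorphic kidney genes 4 fell and 1 rose, also when adjusted over the list alone (median -0.39; camera adjusted p = 0.0682). Acsm3 was at -1.13 ± 0.09, Odc1 at -0.66 ± 0.12 and Cyp2d9 at -0.52 ± 0.38, and without replicate 3 this list passed, with a median of -0.30. Fry and the comparison with random lists also called it. Cyp2d9 was not called without replicate 2 (-0.53), without replicate 3 (-0.32) or with the arrays scaled (-0.60). Pdk4, when exact zeros were taken as values, was at 0.48, and Acot1, Sucla2, Ndufa1, Odc1 and Cyp2d9 were not called.

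Lists of glomerular cell markers did not pass camera. Of 12 podocyte markers 4 were higher and 0 lower, and 4 higher and 1 lower when adjusted over the list alone (median 0.09; camera adjusted p = 0.381). Ptpro rose by 0.66 ± 0.14, Pdpn by 0.66 ± 0.09, Cd2ap by 0.62 ± 0.03 and Actn4 by 0.38. The other 8 did not pass over all genes, and Foxc2 (-0.24) was the member lower when adjusted over the list alone. Ptpro was at 0.08 and not called with exact zeros as values, since a second feature, negative on replicate 1 and at 0 on the others, then entered its average. Fry, which does not compare a list with other genes, called the podocyte list. Nephrin, Nphs1, was at -0.09 ± 0.16 and did not pass (adjusted p = 0.490). Of 20 endothelial and mesangial markers 3 were higher and 1 lower, and 1 and 1 when adjusted over the list alone (median -0.01; camera adjusted p = 0.743). Esm1 was at -1.16 ± 0.32, Nos3 at 0.46 ± 0.04, Thbd at 0.30 and Sox18 at 0.46 ± 0.44. Sox18 was not called without replicate 2 (0.23) or without replicate 3 (0.48), with array medians centred or arrays scaled (0.43 in both), or with features measured on at least 2 arrays. Nos3, when exact zeros were taken as values, was at 0.13, and Nos3, Esm1 and Sox18 were not called.

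Several of the fixed markers gave no usable ratio. No feature was named for Havcr1, Spp1 or C3, and Umod and Kap were listed at 0 on all arrays. Actb had values on 2 arrays that differed in sign (0.23 and -0.47). Gapdh, often used as a reference gene, rose by 0.41 ± 0.11 (adjusted p = 0.00692), and its 12 features measured on all arrays ranged from -0.04 to 0.57. Gapdh, when exact zeros were taken as values, was at 0.22 and not called.

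Of the 31 lists 18 were called with camera, 11 higher and 7 lower, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, while fry called 20, of which 15 were shared with camera. The count of 2698 changed genes fell to 1583 without replicate 2, to 1655 without replicate 3, to 1731 after scaling the arrays and to 612 when exact zeros were taken as values, a setting chosen after seeing the data, and it was 4 when variance was not shared between genes. Of 110 named genes that were called, 51 lost the call with exact zeros as values, and 26 moved by over 1.5 times, 14 of them among the calls lost. Several others, such as Sdc3, Sox9 and Slc12a1, lost the call at an unchanged mean, so without a zero in their own average. These losses came from the fit over all genes, which then held features without spread, and not from the genes' own values. The control pool was 1 sample in 1 dye orientation, so the spread between control mice and a dye effect shared by a gene's features stayed unmeasured.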

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

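The exact-zero setting and the removal of the run of neighbouring features were chosen after seeing the data. None of the 110 called genes of the fixed naming rule, or of the 18 called lists, changed direction under any setting run for it. Genes named outside that rule were not followed across settings. Counts below are features, then genes, then genes higher and genes lower, against 3575, 2698, 1462 and 1236. Scaling the arrays gave 2298, 1731, 941 and 790. Leaving out 1 replicate gave 2034 to 3360 features, 1583 to 2587 genes, 836 to 1380 higher and 734 to 1207 lower, lowest for features and genes without replicate 2; of the 2698 genes, 1541 were also called without replicate 2 and 1605 without replicate 3. With 2 arrays left, 1 residual degree of freedom remained. A change of at least 1.5-fold left 1052, 767, 427 and 340, and of at least 2-fold 289, 214, 128 and 86. A test against 1.2-fold left 1055, 794, 435 and 359, and an adjusted p under 0.01 left 1913, 1443, 756 and 687, as stricter thresholds must leave fewer. Exact zeros as values gave 494, 612, 335 and 277, with 557 of the 612 genes among the 2698. Part of this loss came from the fit over all genes. Sox9, at an unchanged mean, had a limma adjusted p of 0.0947, against 0.000262 in the main fit and 0.1455 without sharing of variance. For Slc12a1 these were 0.0618, 0.000252 and 0.1157. Whether the shared variance or the adjustment over all genes did this was not tested. Without sharing of variance, the test of each row on its own gave 0, 4, 2 and 2, although 2927 features and 2217 genes had an unadjusted p under 0.05; with 2 residual degrees of freedom that test has little power. The other settings (centring, at least 2 arrays, robust prior, median feature, without the run) stayed within 1.5 times, with 2545 to 2716 genes, and limiting values beyond 5 moved nothing, since none was that large. Centring gave 1288 higher and 1352 lower genes, so the share of higher genes went from 54.2% to 48.8% and lower genes became the larger group. Of 110 named genes that were called, 51 were lost with exact zeros as values, 110 without sharing of variance, and 0 to 4 in each other setting; with zeros as values 26 moved by over 1.5 times, 14 of them among the calls lost. The 18 called lists became 0 with an estimated correlation, a test that called 0% of 50 simulated lists of 20 independent genes shifted by 0.5. Larger shifts and correlated genes were not simulated. Fry added the neutrophil, T cell and NK cell, podocyte, sex-dimorphic and oxidative stress lists, random lists the sex-dimorphic list, and leaving out replicate 3 the fatty acid oxidation and sex-dimorphic lists. The chemokine list was also lost under fry, random lists, at least 2 arrays, without replicate 2 and with zeros as values; the proximal tubule and cell cycle lists under fry; the collecting duct list under random lists; and the fat, adrenal and muscle list under random lists, without replicate 3 and with zeros as values. The lowest correlation between arrays, 0.771, was 0.358 without the upper quartile of absolute means and 0.678 with zeros as values. Leaving out features by the mean of the same arrays in itself lowers their correlation, so 0.358 does not show how much the largest changes carry. Signal over background was not used here.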

Other observations

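Tests of the run of neighbouring features and of muscle and brown fat were chosen only after the results were seen; the tests of single features of a gene and of turned signs were written before.

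Xenobiotic and steroid metabolism went both ways. Of 24 measured genes 5 were higher and 8 lower, and 6 and 8 when adjusted over the list alone (median -0.08; camera adjusted p = 0.379). The vitamin D hydroxylase Cyp24a1 rose by 1.43 ± 0.34 and the aldehyde dehydrogenase Aldh1a7 by 1.16 ± 0.18, while Cyp51 was at -1.21 ± 0.05. Renin-angiotensin and vasoactive genes were also mixed, with 4 of 14 higher and 3 lower, and 5 and 4 when adjusted over the list alone (median -0.16; mean 0.03; camera adjusted p = 0.689, so median and mean differ in sign). The prostaglandin receptor Ptger4 rose by 0.75 ± 0.16 and endothelin, Edn1, by 0.70 ± 0.27. Of 13 oxidative stress and metallothionein genes 4 were higher and 1 lower, also when adjusted over the list alone (median 0.18; camera adjusted p = 0.214), a list that fry called. Mt2 rose by 0.81 ± 0.06, heme oxygenase, Hmox1, by 0.65 ± 0.10 and the transcription factor Nfe2l2 by 0.51 ± 0.12, and the cystine transporter Slc7a11 fell (-0.40). Ptger4, when exact zeros were taken as values, was at 0.38, and Ptger4, Edn1, Cyp24a1 and Nfe2l2 were not called.

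Blood cell markers moved apart. The platelet chemokine Pf4 rose by 1.58 ± 0.21, while Car1 (-1.59 ± 0.19) and Slc4a1 (-1.56 ± 0.06), both red cell genes, fell, and the globin genes Hba-a1 (0.32) and Hbb-b2 (0.35) did not pass. Slc4a1 is also a collecting duct gene. The list of 8 had 2 higher and 3 lower, and 4 and 3 when adjusted over the list alone, with a median of 0.23, a mean of -0.08 and a camera test that pointed down (adjusted p = 0.924). Of 20 ribosomal protein genes 7 were higher and 2 lower, also when adjusted over the list alone (median 0.12; camera adjusted p = 0.214), among them Rplp0 (0.66 ± 0.18), Rpsa (0.56 ± 0.09) and Rpl19 (0.53 ± 0.14). Pf4, when exact zeros were taken as values, was at 0.79, Slc4a1 at -0.78 and Rpsa at 0.28, and Rplp0 and Rpl19 were not called.

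Features 15760 to 15773 held 9 of the 109 features with a mean under -1, among them Sdc3, Hes1, Lhx1, Nfkbib and Ebi3. Over 10000 shuffles of positions the densest window of 16 features held at most 4, which argues against position by chance (permutation p = 1e-04, the smallest the shuffles can give). In the run, Akt2 had a mean of -2.19, Psg17 a mean of -1.80, and Kcnj12 lay between -3.40 and -2.29. Other features of Akt2, Kcnj12 and Psg17 elsewhere on the array were at 0.16, -0.35 and -0.044 (median -0.044), which argues against lower transcript levels of these 3 genes and is consistent with a local defect shared by the 3 arrays. This rests on 3 features with other accessions, which may detect other transcripts. For the 5 genes with no other measured feature, lower transcript levels in nephritic kidney and a defect cannot be told apart.

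The changed genes could in part be features with a dye effect, since no dyes were exchanged. Of 366 genes whose called feature had a partner with another accession, 292 or 79.8% shared its sign (exact 95% interval 75.3% to 83.8%), which argues against dye effects of single features as the whole cause. Across 972 such genes the features correlated at r = 0.563, with genes not independent replicates. A dye effect common to all features of a gene stays open. Turning the sign of 1 array gave at most 0 genes against 2698, with 14 to 26 genes at an unadjusted p under 0.05 in limma. So 1 of 4 sets, the real one, gave as many, and 4 sets are too few for a share under 0.05. The shared control pool and dye orientation also make the arrays agree, so turned signs cannot tell a change in nephritis from these.

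Muscle and brown fat transcripts lay among the strongest falls, with Myh1 at -1.96, Cox8b at -1.87, Lpl at -1.54 and Scd1 at -2.14, which might reflect less adhering tissue in the nephritic samples. The other 20 muscle genes had a median of -0.10 (95% bootstrap interval over genes -0.33 to 0.13), with the abundant Mylpf at -0.11 and Myh4 at 0.19. This argues against less skeletal muscle as the whole cause of falls of that size only if these genes were above background. Signal was not used, so genes at background, which would look unchanged whatever the muscle content, could not be set aside. Of all 22, 9 were lower, among them Pvalb (-1.53), Myoz1 (-0.87), Ldb3 (-0.84), Tnnc2 (-0.45) and Tnnt3 (-0.43), and 2 higher. The other 13 brown fat genes had a median of -0.13 (-0.64 to -0.03); 9 of all 16 were lower and 0 higher, but the thermogenic gene Ucp1 was at 0.04. Less brown fat and lower expression in the kidney itself cannot be told apart, because the interval is wide and 7 of the 16 genes are also kidney genes by general knowledge, against 2 of the 22 in the muscle list. Some of both lists had been seen before they were written, and 8 and 5 genes respectively also stand in the fixed lists.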
